A study of Rattus norvegicus with 6 samples.

How the data were processed

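Gene expression was measured in heart muscle of 6 male Wistar rats with 1-colour Agilent arrays, per the labels 1 array per animal. Whether array M25 is a separate animal is in doubt (see the closing section), and values with n = 3 count arrays. In 3 rats the left anterior descending coronary artery was tied, and 6 h later the border zone of the infarct was located by staining and sampled (replicates M17, M24 and M25). The other 3 rats were sham-operated and sampled at the same time (replicates C4, C5 and C6). Total RNA was isolated with TRIzol and labelled with Cy3.

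Per the file headers, the spot signals are intensity values made with Agilent Feature Extraction 11.0.1.1, which subtracts the background and removes spatial trends but does not normalize between arrays. The other columns used, as deposited, are flags of 0 or 1 for each spot (control, outlier, saturated, well above background). The authors also gave a table of values on the log2 scale. Tested on its values, its columns share nearly the same quantiles, with medians of 5.54 in M17 and 5.53 in C6, so it was treated as quantile-normalized. Of its 24529 probes, 24415 matched probes of the scanner files. That table was used only as an alternative. All columns of per-sample values were assigned to a sample.

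The analysis used the processed signal on the log2 scale minus the 75th percentile of each array. Control spots and spots marked as outliers were left out, and the spots of a probe were averaged. Of 24684 probes, 70 lacked a usable spot on at least 1 array and 24614 were carried forward. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which held for 17930 probes. Of these, 17894 were well above background on all border-zone arrays and 11972 on all sham arrays. Far more probes thus entered through the border zone alone than through sham alone. Rises from dim sham signal were therefore testable more often than falls to dim border-zone signal. The border zone was compared with sham by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with statmod 1.5.0, with Benjamini-Hochberg adjustment over all probes tested and a threshold of adjusted p below 0.05. Errors given with log2 fold changes are the standard errors of that fit, with n = 3 arrays per group. Arrays of the dimmer group that were not well above background were raised, where lower, to the lowest signal called so on that array. Where this raised an array, or no array of that group was well above background, the fold is given as a lower bound. Log2 fold changes are not raised. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

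The file headers place the 3 border-zone arrays and sham C4 in 1 scan, and sham C5 and C6 in a scan of their own each. A fit with scan as a block therefore equals a comparison of the border zone with C4 alone. It has no sham replicate: its 2 residual degrees of freedom come from M17, M24 and M25 only, and its p-values hold no spread between sham animals. If M25 is a mixture, that spread is too small. Its values stand beside the pooled ones as "against C4". C5 and C6 hold samples of 1 group only, so their scans give no comparison within the scan.

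Probes were named through their RefSeq accessions in a gene table of the GRCr8 assembly. The array headers name the genome build rn4, and no coordinates were used. Of the carried probes, 14250 were protein-coding, 9 were long noncoding RNA (lncRNA), 6 had another biotype, 1046 had a RefSeq mRNA accession without a match, and 9303 had an accession outside the table. The last class has no biotype here and is described on its own. The planned correlation of lncRNAs with neighbouring coding genes was not run, because no table used here pairs them. A gene was represented by its probe with the highest mean level over all arrays.

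The 33 gene lists (699 memberships), the comparison, the threshold and the rule for naming genes were written before the data were examined. The rule takes the 8 named coding genes with the largest rise and the 8 with the largest fall by pooled log2 fold change, among those past the threshold whose groups do not overlap and that are well above background on all 3 arrays of the brighter group. It further takes up to 4 lncRNA probes per direction, up to 4 passing members per list by absolute fold, the member with the smallest p in a list without one, and the measured members of the list of named lncRNAs. Some genes taken by the rule are not printed. The 8 unnamed transcripts with accessions outside the table were taken by the same ranking after the data were seen. Lists with at least 5 measured members, 32 in all, were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The share of lncRNA probes that passed was compared with that of coding probes by Fisher's exact test. After the data were seen, 5 marker lists of other tissues were added (central neuron, astrocyte, oligodendrocyte, peripheral neuron and Schwann cell, and other organs), each written from textbook markers before it was tested.

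The alternatives set before the data were seen were quantile and median scaling, normexp background correction with an offset of 50, the authors' table, 3 other filters, eBayes with trend and robust, array weights, an unequal-variance test per probe, scan as a block, leaving out each array, stricter thresholds, and for lists an estimated correlation, the mean of a gene's probes and fry. Normexp was run on the median spot signal in place of the mean signal. Alternatives chosen after the data were seen were scan as a random block, the border zone against C4 alone, the border zone without M25 against C4 alone, and the transcripts outside the table in place of lncRNA. The methods were tested on simulated data with the size of these groups. Of 67 probes shifted 2-fold, 23 were recovered; of 67 shifted 4-fold, 49; and of 66 shifted 16-fold, 64; 11 unshifted probes were called. No list was called before a shift, and 3 of 32 were called when 1 list was shifted. The simulated probes varied independently of each other and of scan. These list counts therefore cannot show how the list test behaves when genes are correlated. A mixing share set at 0.3 was recovered as 0.298.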

Results

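Messenger RNA and other transcripts were profiled in the myocardium of 6 rats per the labels, 3 with infarction and 3 sham-operated. The series asks which lncRNAs and mRNAs change in the infarct border zone at 6 h. Well above background were 74.3%, 77.3% and 78.3% of probes on border-zone arrays M17, M24 and M25, 73.7% on sham C4, 51.0% on C5 and 52.4% on C6. The 3 border-zone arrays and C4 share 1 scan, and C5 and C6 have 1 each. No spot was saturated. Replicate spots of a probe differed by a median SD of 0.0724 (C5) to 0.113 (C6) on the log2 scale. The number of arrays limits the precision of every value.

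Several inflammatory transcripts were far higher in the border zone than in sham myocardium. Interleukin 6 (Il6), a cytokine of the acute phase response, rose at least 139-fold (log2 fold change 8.16 ± 0.63, 9.14 against C4, at least 495-fold, n = 3 arrays per group, adjusted p = 0.00197). Pentraxin 3 (Ptx3), a secreted pattern recognition protein, rose 151-fold (7.24 ± 0.30, 7.23 against C4, adjusted p = 0.000649). The neutrophil chemoattractant Cxcl2 rose at least 59.8-fold (6.98 ± 0.36, 6.18 against C4), and Ankrd2, a stretch-responsive protein of striated muscle, rose 111-fold (6.80 ± 0.36, 7.52 against C4). Other large rises, whose order is not settled where sham arrays were at background, were in the neuropeptide galanin (Gal, at least 37.5-fold, 6.51 ± 1.04, 8.76 against C4, at least 133-fold), the secreted lectin Reg3b (at least 74.5-fold, 6.28 ± 0.50, 5.69 against C4), Sectm1b (at least 64.8-fold, 6.09 ± 0.19, 6.25 against C4) and the chemokine Ccl20 (at least 26.2-fold, 5.97 ± 0.87, 5.03 against C4).

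**Figure D1:**
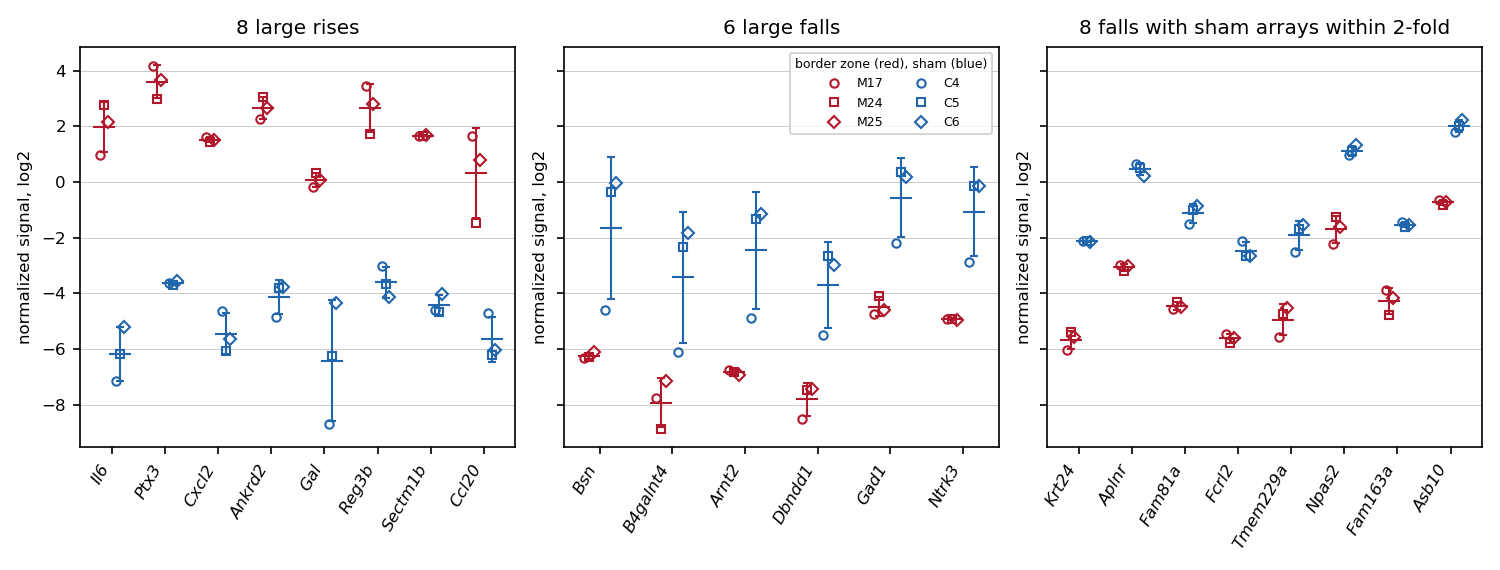
Normalized log2 signal per array for 8 coding genes with large rises, 6 with large falls, and 8 further falls whose sham arrays lay within 2-fold of each other. Points are arrays, bars are group means ± SD (n = 3 arrays per group). Il6 means were 1.97 in the border zone and -6.19 in sham. For Bsn, sham C4 was at -4.59 and C5 and C6 were at -0.35 and -0.040.

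Large pooled falls in 6 coding genes were those of the presynaptic scaffold Bsn (-4.59 ± 1.21, -1.66 against C4), B4galnt4 (at least 13.8-fold, -4.50 ± 1.19, -1.80 against C4, at least 2.13-fold), Arnt2 (at least 20.7-fold, -4.37 ± 1.01, -1.94 against C4), Dbndd1 (at least 12.1-fold, -4.11 ± 0.80, -2.32 against C4, at least 3.53-fold), the GABA-synthesizing enzyme Gad1 (-3.92 ± 0.70, -2.27 against C4) and the neurotrophin receptor Ntrk3 (-3.87 ± 0.76, -2.04 against C4). All 6 were higher in sham C5 and C6 than in sham C4, with log2 differences of C4 from the mean of C5 and C6 between -4.40 (Bsn) and -2.48 (Gad1). Markers of central nervous tissue were also higher on C5 and C6. Of 79 measured markers of central neurons, astrocytes and oligodendrocytes, 74 (93.7%) were higher on both C5 and C6 than on every other array; arrays C5 and C6 have higher background, so the lists of other tissues serve as the comparison. By list these were 48 of 51 central neuron, 12 of 13 astrocyte and 14 of 15 oligodendrocyte markers, against 7 of 14 of peripheral neurons and Schwann cells and 8 of 18 of other organs. Well above background on both C5 and C6 were 64 of the 79, 9 of the 14 and 1 of the 18. The count for other organs thus rests mostly on background signal. The median of the first 3 lists was 3.45 log2 higher in C5 and C6 than in C4, and -0.15 in the border zone relative to C4. With C4 raised to its lowest signal well above background, the first of these was 3.03. Nefl, a neurofilament, was at least 111-fold, Aqp4, an astrocyte water channel, 122-fold and Mbp, a myelin protein, 12.7-fold higher in C5 and C6 than in C4. Of 1845 called falls, 112 (6.07%) were at least 2-fold higher in C5 and C6 than in C4, about the 6.53% of all probes tested. Among the 144 of 4-fold or more, which high C5 and C6 values themselves favour, 66 (45.8%) were.

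**Figure D2:**
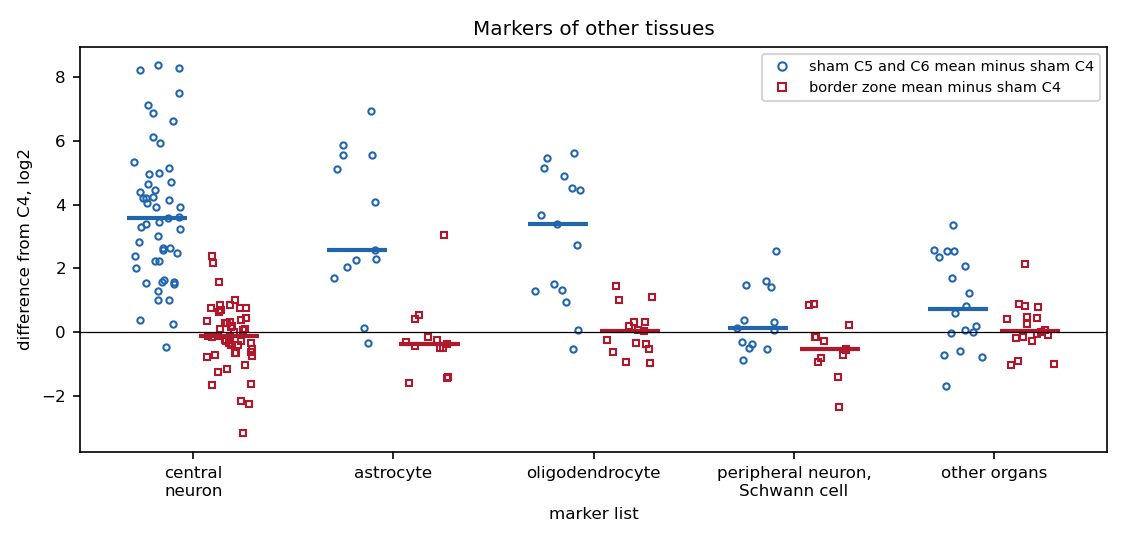
Log2 difference from sham C4 for each marker gene of 5 tissue groups. Blue circles are the mean of sham C5 and C6, red squares the mean of the 3 border-zone arrays, lines are medians. The median of the central neuron genes was 3.57 in C5 and C6 and -0.12 in the border zone.

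Other falls had sham arrays within 2-fold of each other and passed both pooled and against C4 alone, a fit without sham spread. Chosen after their values were seen, they were Krt24, a keratin (-3.54 ± 0.18, -3.57 against C4), Aplnr, the apelin receptor (-3.52 ± 0.15, -3.72 against C4), Fam81a (-3.33 ± 0.20, -2.95 against C4), Fcrl2 (-3.15 ± 0.19, -3.52 against C4), Tmem229a (-3.03 ± 0.38, -2.43 against C4), the clock transcription factor Npas2 (-2.84 ± 0.27, -2.66 against C4), Fam163a (-2.75 ± 0.25, -2.86 against C4) and Asb10 (-2.74 ± 0.15, -2.52 against C4). The limit on sham spread itself keeps these standard errors small. Both fits share C4 and the border-zone arrays, so the fit against C4 is not separate support.

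In all, 3460 of 17930 probes passed (19.3%), 1615 higher and 1845 lower, and 788 and 741 of these changed at least 2-fold. Of 11312 coding probes, 1107 rose and 1346 fell. By gene, 1089 of 11001 rose and 1309 fell. For every probe that passed, the 3 border-zone arrays lay on 1 side of the 3 sham arrays, and the groups did not overlap for 7838 probes (43.7%). Of the 3460, 1182 were at least 2-fold changed the same way against C4 alone. With scan as a block, which leaves C4 as the only sham array and so no sham spread, 1511 rose and 1345 fell, 980 and 972 of them in common with the pooled fit. Of the 1845 falls, 136 had sham signal above background on only some or none of its arrays. Median scaling gave 67.6% of passing probes as higher, against 46.7%. The median log2 fold change of all probes was -0.026, against 0.094 with quantile scaling, 0.16 with median scaling, -0.35 with normexp and -0.26 without a filter. Border-zone array M25 lay between M17 and M24 in 98.4% of the 557 probes that differed over 2-fold between those. Leaving out 1 array left 1439 passing probes without M17, 1167 without M24, 509 without M25, 7308 without C4, 1405 without C5 and 2366 without C6. Without C4, no sham array shares the scan of the border zone. That count therefore cannot be separated from differences between scans or from the nervous tissue transcripts of C5 and C6. Without M25 and against C4 alone, 76 passed. Of the 16 coding genes with the largest pooled log2 changes, Il6, Ptx3, Cxcl2, Ankrd2, Reg3b and Sectm1b kept their calls whichever array was left out. The call of Gal ended without M17 (adjusted p = 0.0505), M24 (0.0577) or M25 (0.070). None of the 6 large falls above kept its call in limma without M17, M24, M25 or C5. Leaving out M17, M24 and C5 in turn, the adjusted p of Gad1 was 0.0669, 0.0606 and 0.0568, and that of Bsn 0.133, 0.141 and 0.132, and 0.108 without C6. With scan as a block, Ccl20 (adjusted p = 0.0804), B4galnt4 (0.169) and Dbndd1 (0.0579) did not pass. Genes that passed in fewer than 10 settings included B4galnt4 (5), Irf7 (6), Areg (6), Bsn (8), Cspg4 (8), Dbndd1 (9) and Gdf15 (9). The genes taken by the naming rule and the 8 transcripts outside the gene table numbered 126. Of these, 37 lost their call without M17, 50 without M24, 76 without M25, 2 without C4, 47 without C5 and 22 without C6. Without M25 the adjusted p was 0.0599 for Ccl20 and 0.0881 (Gad1) to 0.151 (Bsn) for the 6 falls.

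**Figure D3:**
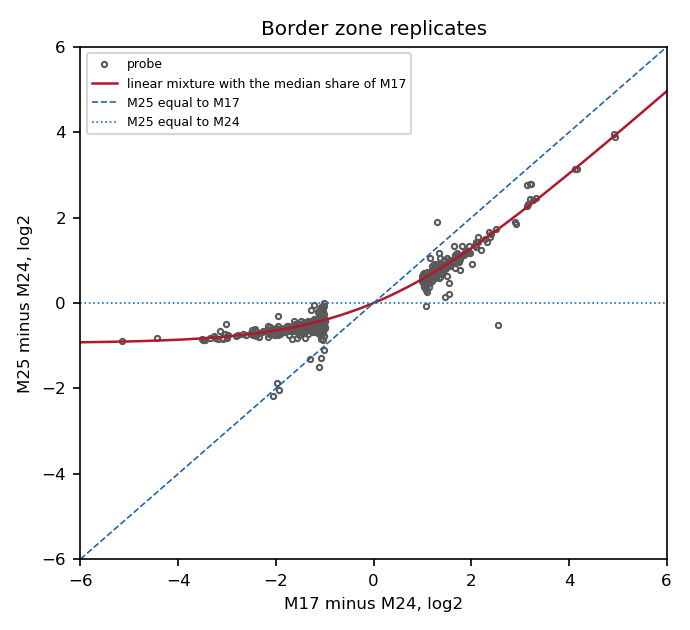
Each point is a probe that differed over 2-fold between M17 and M24. The x axis is M17 minus M24 and the y axis M25 minus M24, both in log2 units, and the curve is a linear mixture at the median share of M17, 0.479. M25 lay between M17 and M24 for 98.4% of these probes.

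Of 32 gene lists tested, camera called 16 higher and 2 lower at the preset correlation. It called 0 with an estimated correlation, where 9 had an unadjusted p under 0.05. Other splits of the 6 arrays called up to 16 lists at the preset correlation. The number of calls there does not by itself set the border zone apart from sham. Of the inflammatory lists, 3 were higher. Among inflammatory cytokines and their receptors, of 19 measured members 14 rose and 5 did not pass (15 rose, adjusted over the list alone). Examples beside Il6 were the decoy receptor Il1r2 (3.86 ± 0.20, 3.75 against C4), the receptor antagonist Il1rn (3.68 ± 0.28, 3.28 against C4) and Il1b (3.44 ± 0.21, 3.21 against C4). Over the list, the median log2 fold change was 1.71, 1.53 against C4 (camera adjusted p = 4.08e-10, and adjusted p = 0.141 with an estimated correlation). Blocking on scan, 14 rose, and leaving out M25, 12 rose. Among chemokines, of 22 measured members 11 rose, 1 fell and 10 did not pass (14 rose and 2 fell, adjusted over the list alone), with Cxcl1 (5.55 ± 0.24, 5.25 against C4) and the monocyte attractant Ccl7 (4.51 ± 0.35, 3.83 against C4) after Cxcl2 and Ccl20. The list's members had a median log2 fold change of 1.01, 0.72 against C4 (camera adjusted p = 5.42e-06, and adjusted p = 0.165 with an estimated correlation). Without M25, 5 rose, and with scan as a block, 9 rose. For NF-kappaB feedback and leukocyte adhesion, of 13 measured members 10 rose and 3 did not pass (12 rose, adjusted over the list alone), among them Ptx3, the endothelial selectin Sele (2.87 ± 0.27, 2.65 against C4), Bcl3 (2.66 ± 0.17, 2.63 against C4) and Socs3 (at least 3.51-fold, 2.57 ± 0.45, 1.59 against C4, 0.57 with normexp). As a list they had a median log2 fold change of 1.98, 1.59 against C4 (camera adjusted p = 2.19e-07, and adjusted p = 0.165 with an estimated correlation). When M25 was left out, 4 rose, and when scan was a block, 7 rose. Among interferon response genes, of 19 measured members 2 fell and 17 did not pass (2 rose and 4 fell, adjusted over the list alone), Gbp5 at -1.02 ± 0.24, -1.11 against C4 and Irf7 at -0.74 ± 0.19, -0.84 against C4. Their median log2 fold change was -0.30, -0.76 against C4 (camera adjusted p = 0.166), and with scan as a block the list was lower (adjusted p = 0.0120, range over its alternatives 0.00386 to 0.749). Without C6 it was lower too (adjusted p = 0.0219). The calls of Gbp5 and Irf7 ended with scan as a block.

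Several markers of myeloid cells rose. For neutrophil markers, of 11 measured members 9 rose and 2 did not pass (10 rose, adjusted over the list alone), with the calgranulin S100a8 (5.21 ± 0.43, 6.11 against C4), the receptor Csf3r (at least 6.23-fold, 3.82 ± 0.13, 3.64 against C4, 0.98 with normexp), Pglyrp1 (at least 3.76-fold, 3.15 ± 0.22, 3.63 against C4, 0.37 with normexp) and the cathelicidin Camp (at least 6.54-fold, 2.99 ± 0.38, 3.68 against C4, 0.99 with normexp). The median log2 fold change was 2.93, 2.92 against C4 (camera adjusted p = 1.12e-06, and adjusted p = 0.141 with an estimated correlation). With scan as a block, 9 rose, and without M25, 4 rose. For monocyte and macrophage markers, of 23 measured members 13 rose, 3 fell and 7 did not pass (15 rose and 4 fell, adjusted over the list alone). Rises included the lectin Clec4e (at least 7.48-fold, 3.50 ± 0.68, 4.31 against C4, 1.15 with normexp), the endotoxin co-receptor Cd14 (2.07 ± 0.17, 1.96 against C4) and lysozyme Lyz2 (1.70 ± 0.18, 1.34 against C4). The fractalkine receptor Cx3cr1 was called lower, but C5 and C6 were at background, so no fold is given. The other falls, chosen after their values were seen, were Trem2 (-1.33 ± 0.17, -1.37 against C4) and Adgre1 (-0.77 ± 0.19, -1.11 against C4). Over the list, the median log2 fold change was 0.75, 0.63 against C4 (camera adjusted p = 0.000346, and adjusted p = 0.141 with an estimated correlation). Blocking on scan, 9 rose and 3 fell, and leaving out M25, 3 rose. For lymphocyte markers, of 14 measured members 1 rose and 13 did not pass (0 adjusted over the list alone, 2 at an unadjusted p under 0.05), Klrd1 at 0.54 ± 0.14, 0.70 against C4, with a median log2 fold change of 0.28, 0.011 against C4 (camera adjusted p = 0.0534); without M17 the list's adjusted p was 0.00830, and its range over the alternatives was 0.00830 to 0.538. For red cell and platelet markers, of 10 measured members 1 rose and 9 did not pass (1 rose, adjusted over the list alone), Pf4 at 0.82 ± 0.15, 0.56 against C4, with a median log2 fold change of -0.90, -1.0 against C4 (camera adjusted p = 0.580). The member Hbb, chosen after its values were seen, had a normalized log2 signal of 5.90, 2.68 and 5.47 on M17, M24 and M25. On C4, C5 and C6 it was at 6.02, 5.61 and 6.05. Blocking on scan ended the calls of Cx3cr1 and Klrd1.

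**Figure D4:**
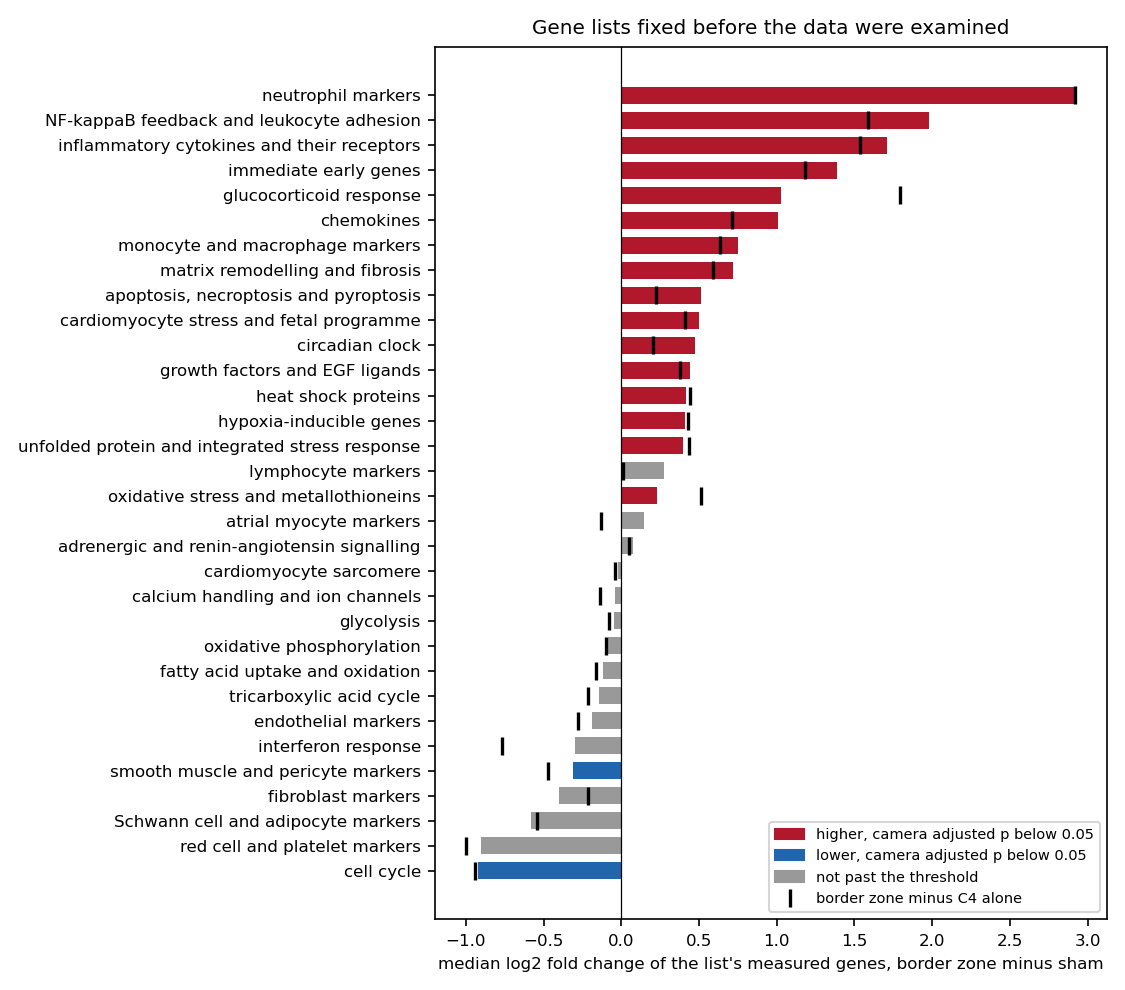
Median log2 fold change of each gene list, border zone against sham (bars), with the median against sham C4 alone (ticks). Neutrophil markers had the largest median, 2.93, and cell cycle genes had -0.92.

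Part of the immediate early and stress genes rose. Among immediate early genes, of 24 measured members 13 rose, 1 fell and 10 did not pass (15 rose and 1 fell, adjusted over the list alone), with Fosl1 (at least 20.1-fold, 5.81 ± 0.89, 7.86 against C4, at least 71.3-fold), Myc (4.37 ± 0.11, 4.28 against C4), Atf3 (3.13 ± 0.66, 2.49 against C4) and Fos (2.39 ± 0.46, 1.91 against C4). The phosphatase Dusp1, chosen after its values were seen, fell (-0.67 ± 0.14, -0.55 against C4). The list's members had a median log2 fold change of 1.39, 1.18 against C4 (camera adjusted p = 1.12e-06, and adjusted p = 0.273 with an estimated correlation). Without M25, 5 rose, and with scan as a block, 9 rose. Among oxidative stress genes and metallothioneins, of 19 measured members 6 rose and 13 did not pass (7 rose, adjusted over the list alone): the metallothionein Mt2A (5.86 ± 0.39, 6.73 against C4), heme oxygenase Hmox1 (3.78 ± 0.17, 4.09 against C4), Mt1 (3.15 ± 0.35, 3.52 against C4) and Txnrd1 (1.19 ± 0.19, 1.37 against C4) led. As a list they had a median log2 fold change of 0.23, 0.51 against C4 (camera adjusted p = 0.0107, and adjusted p = 0.401 with an estimated correlation). When M25 was left out, 3 rose, and when scan was a block, 7 rose. Among genes of the unfolded protein and integrated stress response, of 20 measured members 7 rose and 13 did not pass (7 rose, adjusted over the list alone), with Asns (1.59 ± 0.30, 2.21 against C4), Trib3 (1.5 ± 0.21, 1.79 against C4), Atf6 (at least 2.21-fold, 1.39 ± 0.35, 1.00 against C4, 0.30 with normexp) and Dnajc3 (1.30 ± 0.27, 0.73 against C4). The median log2 fold change was 0.40, 0.44 against C4 (camera adjusted p = 0.0104, and adjusted p = 0.168 with an estimated correlation). With scan as a block, 4 rose, and without M25, no member passed in limma, with 7 at an unadjusted p under 0.05. For heat shock proteins, of 13 measured members 3 rose and 10 did not pass (3 rose and 1 fell, adjusted over the list alone): Hspb1 (1.28 ± 0.10, 1.36 against C4), Hsp90aa1 (1.07 ± 0.22, 0.76 against C4) and Bag3 (0.79 ± 0.14, 0.71 against C4). Over the list, the median log2 fold change was 0.41, 0.44 against C4 (camera adjusted p = 0.0392, and adjusted p = 0.196 with an estimated correlation). Blocking on scan, 3 rose, and leaving out M25, 1 rose. The heat shock list's adjusted p was 0.0657 without M24 and 0.0812 without C4 (range over its alternatives 0.000451 to 0.196), and without C4 that of the oxidative stress list was 0.0812 (range 2.53e-05 to 0.401) and that of the unfolded protein list 0.0583 (range 0.000285 to 0.168). When scan was a block, Atf3, Fos, Hsp90aa1, Dnajc3 and Dusp1 did not pass.

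For hypoxia-inducible genes, of 19 measured members 7 rose, 1 fell and 11 did not pass (7 rose and 1 fell, adjusted over the list alone). Examples were Ndrg1 (1.57 ± 0.19, 1.47 against C4), Bhlhe40 (1.22 ± 0.22, 1.58 against C4, 0.48 in its lowest alternative) and endothelin 1 (Edn1, at least 2.05-fold, 1.28 ± 0.24, 1.36 against C4, but -0.079 with normexp). Vegfa, an angiogenic factor chosen after its values were seen, fell (-0.81 ± 0.17, -0.50 against C4). The list's members had a median log2 fold change of 0.41, 0.43 against C4 (camera adjusted p = 0.00264, and adjusted p = 0.409 with an estimated correlation). Without M25, 2 rose, and with scan as a block, 5 rose. In apoptosis, necroptosis and pyroptosis, of 26 measured members 10 rose, 3 fell and 13 did not pass (10 rose and 3 fell, adjusted over the list alone). Rises included the necroptosis kinase Ripk3 (2.41 ± 0.32, 1.91 against C4) and the growth arrest genes Gadd45a (2.39 ± 0.23, 1.88 against C4), Gadd45g (2.05 ± 0.22, 2.09 against C4) and Gadd45b (1.96 ± 0.40, 1.96 against C4), and falls, chosen after their values were seen, included the death receptor Fas (-0.67 ± 0.14, -0.47 against C4, above background on only 1 of the sham arrays) and Bnip3l (-0.50 ± 0.10, -0.55 against C4). As a list they had a median log2 fold change of 0.51, 0.23 against C4 (camera adjusted p = 0.00676, and adjusted p = 0.355 with an estimated correlation). When M25 was left out, 4 rose, and when scan was a block, 7 rose and 1 fell. Among glucocorticoid response genes, of 13 measured members 8 rose, 1 fell and 4 did not pass (9 rose and 1 fell, adjusted over the list alone), with Lcn2 (2.93 ± 0.43, 2.92 against C4), Pdk4 (2.78 ± 0.40, 2.46 against C4), Sult1a1 (2.49 ± 0.18, 2.21 against C4) and Zbtb16 (2.31 ± 0.27, 1.85 against C4). Some members are on other lists too: Lcn2 on the neutrophil list, Pdk4 on the fatty acid list and Dusp1, which fell, on the immediate early list. The call is thus not separate from those lists. Over the glucocorticoid list, the median log2 fold change was 1.03, 1.80 against C4 (camera adjusted p = 0.000588, and adjusted p = 0.196 with an estimated correlation). With scan as a block, 6 rose, and without M25, 2 rose. The circadian clock list went both ways: of 13 measured members 4 rose, 2 fell and 7 did not pass (4 rose and 2 fell, adjusted over the list alone). The activators Npas2 and Bmal1 (-1.90 ± 0.29, -1.89 against C4) fell, and Ciart (2.42 ± 0.13, 2.51 against C4) and Per2 (1.87 ± 0.34, 2.61 against C4) rose. Over the list, the median log2 fold change was 0.48, 0.20 against C4 (camera adjusted p = 0.0392, and adjusted p = 0.196 with an estimated correlation). Blocking on scan, 5 rose and 1 fell, and leaving out M25, 1 rose and 1 fell. The clock list's adjusted p was 0.0603 without M17, 0.0643 without M24 and 0.0616 without C4 (range over its alternatives 0.00205 to 0.196). The calls of Pdk4, Edn1, Ripk3, Gadd45b, Bmal1, Lcn2, Vegfa and Fas ended with scan as a block.

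Among genes of the cell cycle, of 15 measured members 10 fell and 5 did not pass (10 fell, adjusted over the list alone). The largest falls were in cyclins Ccnd1 (-2.50 ± 0.20, -2.17 against C4), Ccnb2 (-2.22 ± 0.45, -2.61 against C4), Ccna2 (-2.07 ± 0.28, -2.38 against C4) and Ccnb1 (-1.87 ± 0.35, -2.28 against C4). The list's members had a median log2 fold change of -0.92, -0.94 against C4 (camera adjusted p = 7.19e-05, and adjusted p = 0.141 with an estimated correlation). Without M25, 2 fell, and with scan as a block, 9 fell. In matrix remodelling and fibrosis, of 26 measured members 11 rose, 1 fell and 14 did not pass (14 rose and 3 fell, adjusted over the list alone). The protease inhibitor Timp1 (3.87 ± 0.17, 4.09 against C4), hyaluronan synthase Has1 (3.65 ± 0.49, 3.46 against C4), Mmp9 (at least 6.86-fold, 2.81 ± 0.56, 3.77 against C4) and Adamts1 (2.60 ± 0.12, 2.64 against C4) rose, and Loxl2, chosen after its values were seen, fell (-0.92 ± 0.13, -0.79 against C4). As a list they had a median log2 fold change of 0.72, 0.59 against C4 (camera adjusted p = 0.000188, and adjusted p = 0.168 with an estimated correlation). When M25 was left out, 4 rose, and when scan was a block, 7 rose and 1 fell. Among growth factors and EGF ligands, of 22 measured members 4 rose, 2 fell and 16 did not pass (6 rose and 2 fell, adjusted over the list alone), with Fgf2 (at least 8.10-fold, 3.6 ± 0.22, 3.78 against C4), Areg (at least 3.6-fold, 2.93 ± 0.77, 3.06 against C4, 0.66 with normexp), Pgf (2.85 ± 0.44, 3.52 against C4) and Hbegf (1.97 ± 0.26, 1.63 against C4) higher and, chosen after their values were seen, Fgf9 (-1.86 ± 0.27, -2.15 against C4) and Vegfc (-1.21 ± 0.15, -1.16 against C4) lower. At their lowest over the alternatives, Fgf2 was at 1.29 and Hbegf at 0.78. Areg did not pass without M24 (adjusted p = 0.124), M25 (0.167), C4 (0.0677), C5 (0.129) or C6 (0.0858). The median log2 fold change was 0.44, 0.38 against C4 (camera adjusted p = 0.0392, and adjusted p = 0.196 with an estimated correlation). With scan as a block, 3 rose and 4 fell, and without M25, 1 rose. The list's call ended with scan as a block (adjusted p = 0.291, range over the alternatives 0.00527 to 0.551), and without C4 (0.0583), C5 (0.0875) or C6 (0.0607). Blocking on scan ended the calls of Has1, Areg, Hbegf and Ccnb2.

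Among genes of the cardiomyocyte stress and fetal programme, of 14 measured members 5 rose and 9 did not pass (7 rose, adjusted over the list alone): Ankrd2, Fhl1 (2.46 ± 0.21, 2.41 against C4), Gdf15 (at least 1.95-fold, 2.20 ± 0.47, 1.92 against C4, 0.039 with normexp) and the calcineurin inhibitor Rcan1 (1.28 ± 0.18, 0.99 against C4) led. The call of Gdf15 ended without M24 (adjusted p = 0.0714), M25 (0.12), C5 (0.0912) or C6 (0.0664). Over the list, the median log2 fold change was 0.50, 0.41 against C4 (camera adjusted p = 0.000955, and adjusted p = 0.168 with an estimated correlation). Blocking on scan, 3 rose, and leaving out M25, 2 rose. Among sarcomere genes, of 13 measured members 1 rose and 12 did not pass (1 rose, adjusted over the list alone): Myot rose (2.59 ± 0.17, 2.73 against C4). Their median and mean differed in sign, with a median of -0.018 and a mean of 0.18, and camera's direction was that of the mean (camera adjusted p = 0.532). Among calcium handling genes and ion channels, of 24 measured members 1 rose, 5 fell and 18 did not pass (1 rose and 8 fell, adjusted over the list alone). The potassium channel genes Kcna4 (-1.22 ± 0.20, -0.95 against C4), Kcnd3 (-0.99 ± 0.17, -0.66 against C4) and Kcnh2 (-0.97 ± 0.12, -0.81 against C4) fell and the sodium-calcium exchanger Slc8a1 rose (0.87 ± 0.17, 1.01 against C4). These 24 had a median log2 fold change of -0.042, -0.14 against C4 (camera adjusted p = 0.404). Among genes of adrenergic and renin-angiotensin signalling, of 18 measured members 2 rose, 1 fell and 15 did not pass (4 rose and 1 fell, adjusted over the list alone), with Rgs2 (1.35 ± 0.18, 1.1 against C4), Ednrb (1.2 ± 0.15, 0.94 against C4) and Npr1 (-0.63 ± 0.12, -0.53 against C4) and a median log2 fold change of 0.076, 0.050 against C4 (camera adjusted p = 0.488). When scan was a block, Kcna4, Slc8a1, Gdf15 and Npr1 did not pass.

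No list of energy metabolism genes was called by camera. For fatty acid uptake and oxidation, of 27 measured members 2 rose, 4 fell and 21 did not pass (2 rose and 4 fell, adjusted over the list alone). The pyruvate dehydrogenase kinase Pdk4 and the thioesterase Acot1 (1.11 ± 0.19, 0.90 against C4, 0.10 with normexp) rose, and Ucp3 (-1.36 ± 0.30, -1.45 against C4) and the lipid regulator Ppara (-1.09 ± 0.21, -0.73 against C4) fell. These 27 had a median log2 fold change of -0.12, -0.16 against C4 (camera adjusted p = 0.626). In glycolysis, of 20 measured members 3 rose, 1 fell and 16 did not pass (3 rose and 1 fell, adjusted over the list alone). The lactate transporter Slc16a3 (2.42 ± 0.23, 2.69 against C4), the glucose transporter Slc2a1 (1.88 ± 0.28, 2.22 against C4) and hexokinase Hk2 (0.76 ± 0.14, 1.01 against C4) rose and the kinase Pfkfb2 fell (-2.71 ± 0.14, -2.91 against C4). The median and mean differed in sign here too, at -0.049 and 0.052, with camera's direction that of the mean (camera adjusted p = 0.928). By limma 0 of 16 tricarboxylic acid cycle members passed, with 1 at an unadjusted p under 0.05 (Idh2, -0.42 ± 0.14, -0.39 against C4, adjusted p = 0.0841), and their median log2 fold change was -0.14, -0.22 against C4 (camera adjusted p = 0.431). By limma 0 of 24 oxidative phosphorylation members passed, with 2 at an unadjusted p under 0.05 (the smallest for Uqcrfs1, -0.41 ± 0.16, -0.26 against C4, adjusted p = 0.128), and their median log2 fold change was -0.084, -0.095 against C4 (camera adjusted p = 0.488). The calls of Pdk4, Ucp3, Acot1 and Ppara ended with scan as a block.

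Markers of other cells of the heart went both ways. For smooth muscle and pericyte markers, of 12 measured members 1 rose, 4 fell and 7 did not pass (1 rose and 4 fell, adjusted over the list alone), with Abcc9 (-1.02 ± 0.14, -0.87 against C4), Smtn (-0.90 ± 0.11, -0.81 against C4) and Myocd (-0.61 ± 0.12, -0.66 against C4) lower and Cspg4 higher (0.89 ± 0.22, 0.41 against C4). The median log2 fold change was -0.31, -0.47 against C4 (camera adjusted p = 0.0392, and adjusted p = 0.401 with an estimated correlation), and the call ended without M17 (adjusted p = 0.0714), M25 (0.0570) or C4 (0.218; range over its alternatives 0.0128 to 0.401). Without M25, no member passed in limma, with 5 at an unadjusted p under 0.05, and with scan as a block, 3 fell. For endothelial markers, of 12 measured members 1 rose, 4 fell and 7 did not pass (3 rose and 5 fell, adjusted over the list alone): Aplnr, Emcn (-0.95 ± 0.18, -0.80 against C4), Sox18 (-0.77 ± 0.18, -0.81 against C4) and the tight junction gene Cldn5 (-0.71 ± 0.13, -0.84 against C4) fell and Flt1, chosen after its values were seen, rose (at least 1.17-fold, 0.49 ± 0.12, 0.34 against C4). These 12 had a median log2 fold change of -0.19, -0.28 against C4 (camera adjusted p = 0.488). For fibroblast markers, of 13 measured members 3 rose, 3 fell and 7 did not pass (3 rose and 6 fell, adjusted over the list alone), with Tcf21 (1.84 ± 0.13, 1.92 against C4) and Mgp (0.80 ± 0.12, 0.64 against C4) higher and the collagens Col3a1 (-1.84 ± 0.31, -2.07 against C4) and Col1a2 (-1.02 ± 0.21, -1.28 against C4) lower, and a median log2 fold change of -0.40, -0.21 against C4 (camera adjusted p = 0.842). Fry gave this list the opposite direction, up (adjusted p = 0.450). For atrial myocyte markers, of 10 measured members 2 rose and 8 did not pass (3 rose and 1 fell, adjusted over the list alone), Kcnj5 (0.79 ± 0.12, 0.93 against C4) and Clu (0.77 ± 0.13, 0.93 against C4), with a median log2 fold change of 0.15, -0.13 against C4 (camera adjusted p = 0.246). For Schwann cell and adipocyte markers, of 7 measured members 1 fell and 6 did not pass (1 fell, adjusted over the list alone), with a median log2 fold change of -0.58, -0.54 against C4 (camera adjusted p = 0.246). Blocking on scan ended the calls of Emcn, Sox18, Col3a1, Col1a2, Cspg4, Myocd and Flt1.

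The lncRNA class was small, as it held only probes that the gene table classes as lncRNA. Any noncoding transcripts among the probes with an accession outside the table are not in it. Of 6 tested lncRNA probes, 2 rose and 0 fell by limma, and 3 were at an unadjusted p under 0.05. Gas5, a host gene of small nucleolar RNAs, rose 4.33-fold (2.11 ± 0.23, 1.62 against C4, adjusted p = 0.00470) and 2810025M15Rikl rose 2.5-fold (1.32 ± 0.14, 1.08 against C4, adjusted p = 0.00453). Of the named lncRNA list, 3 members were measured. Beside Gas5, the imprinted H19 was at 1.72 ± 0.50, 2.14 against C4 (adjusted p = 0.0625) and Rpph1, the RNA of ribonuclease P, at 0.54 ± 0.35, 1.21 against C4 (adjusted p = 0.313). These passed in 5 and 2 alternatives, H19 among others without M17 (adjusted p = 0.0246). The share of lncRNA probes that passed, 33.3%, and that of coding probes, 21.7%, gave p = 0.617 by Fisher's exact test (two-sided, probes are not independent replicates), but p = 0.0144 without M17 and 0.0177 without M25. Of 5827 probes with an accession outside the gene table, 432 rose and 398 fell (14.2%, p = 7.57e-33 against coding probes by Fisher's exact test). From the dimmest to the brightest of 4 equal groups of probes by level, 5.12%, 15.9%, 23.6% and 22.3% of these passed, against 7.81%, 24%, 28.4% and 22.3% of coding probes (adjusted p = 0.000745, 5.95e-10, 0.00254 and 1, Fisher's exact test). Large rises outside the table were those of MRuc008qhz (5.74 ± 0.31, 6.25 against C4), XR_006843 (at least 5.32-fold, 3.13 ± 0.56, 4.01 against C4, 0.63 with normexp), DQ266361 (2.93 ± 0.44, 2.16 against C4) and EF424788 (at least 5.22-fold, 2.89 ± 0.49, 3.48 against C4, 0.77 with normexp). Large falls were those of MRAK090394 (at least 55.2-fold, -7.46 ± 1.82, -3.03 against C4, at least 2.55-fold), MRAK042828 (-4.28 ± 0.49, -3.15 against C4), BC091372 (-3.60 ± 0.83, -1.62 against C4) and MRAK138918 (-3.55 ± 0.50, -2.39 against C4), and in all 4 sham C4 was lower than C5 and C6, by log2 differences of -6.65, -1.69, -2.98 and -1.75.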

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

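The tests of the nervous tissue transcripts and of array M25 were chosen only after the results were seen, and the counts over splits of the arrays were planned.

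Transcripts of central nervous tissue were high in sham C5 and C6 and low in sham C4 and the border zone. A general difference between scans is argued against, since the markers' median lay at percentile 100 of 10000 random lists matched on level, whose highest median was 0.45 against 3.45 (3.03 with C4 raised to its lowest signal well above background). A fall in the border zone is argued against by C4, which had no infarct and whose median lay at -3.45 relative to C5 and C6. RNA of central nervous tissue in samples C5 and C6 may account for it, as 93.7% of the 79 markers were highest there, with Stmn2 at least 99.2-fold, Nefl at least 111-fold and Gfap 47.4-fold above C4, while 13 of the markers are also expressed in heart (95.5% without these) and peripheral neuron and Schwann cell markers and those of other organs were 0.22 and 0.71 above C4. How such RNA came there was not tested.

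Array M25 lay between M17 and M24. Over the 76 probes that differed over 4-fold between those, the linear signal of M25 gave a share of M17 of 0.479, with a middle 50% only 0.0386 wide and medians of 0.486 and 0.477 for probes higher in M17 and in M24. This may come from RNA of M17 and M24 mixed in sample M25. A separate animal with an intermediate response cannot be told apart from this by the share of probes between, 98.4%, which a mixture gives too. Over 17894 probes well above background on these arrays, M25 differed from the best-fitting mixture by a residual SD of 0.126 log2. The SD between M17 and M24 over these probes was 0.433. This small residual and the narrow share argue against a separate animal for the probes they cover. For comparison, C5 lay between C4 and C6 in 79.2% of probes, with a middle 50% 0.280 wide and a residual SD of 0.25, against 0.757 between C4 and C6. If M25 is a mixture, it is not an independent animal, and the count of passing probes without it was 509 against 3460.

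Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split gave the most: 3460 probes, 2453 coding probes and 18 lists, and the highest of the other splits gave 0, 0 and 16 (limma and camera). The 16 lists came from M17 with C4 and C5 and from M17 with C4 and C6, each against the rest.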

How the results depend on the processing

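Of the values below, those with scan as a random block, against C4 alone, and with transcripts outside the table were chosen only after the results were seen. Leaving out 1 array gave 286 to 3738 probes higher (fewest without M25, most without C4), 223 to 3570 lower, 231 to 2164 coding probes higher, 176 to 2516 lower, 2 to 3 lncRNA probes higher, 11 to 16 lists higher, 1 to 3 lists lower, and p = 0.0144 to 0.697 for the lncRNA share (Fisher's exact test). Leaving out an array lowers the residual degrees of freedom. Without C4, scan and group cannot be told apart. C4 differed from C5 and C6 by an SD of 0.773 and 0.896 on the log2 scale, and these from each other by 0.592. Over probes above background on all arrays these were 0.650, 0.730 and 0.281. Median scaling gave 929 lower (690 coding); normexp gave 1004 higher (731 coding). Without a filter, 791 were higher and 1035 lower (603 and 743 coding) of 24614 tested. Array weights gave 6485 and 5571 (3744 and 3902 coding) and 4 lncRNAs higher, with M25 weighted 411 and the rest at most 1.26. An unequal-variance test per probe gave 298 and 306 (238 and 234 coding) and 0 lncRNAs, against 2 by limma, where 3 had an unadjusted p under 0.05. Requiring 2-fold left 788 and 741 (544 and 546 coding), and adjusted p below 0.01 left 448 and 442 (360 and 331 coding) with p = 0.0476 for the lncRNA share (Fisher's exact test). Above background on all arrays the share's p was 0.0481. Without M25 and against C4 alone, 65 were higher and 11 lower (56 and 6 coding), with 0 lncRNAs. Transcripts outside the table turned the share's direction (p = 7.57e-33, Fisher's exact test). Lists lower numbered 1 with quantile or median scaling, normexp, the authors' table, no filter or all arrays above background, and 4 by fry, which added the endothelial (adjusted p = 0.000140) and calcium handling lists (0.0178). With an estimated correlation 0 lists were higher and 0 lower by camera, with 9 at an unadjusted p under 0.05, and by fry 16 were higher. Edn1 turned to -0.079 with normexp. The cause of these shifts was not tested, except where fewer genes, arrays or a stricter threshold give it. Of 126 named genes, the side of the threshold held for 120 with quantile scaling, 90 with scan as a block, 50 without M25 and 32 with the unequal-variance test. Scan as a random block gave 2081 higher and 2249 lower. No paired analysis was possible because no replicate number is shared between the groups. On C5 and C6 fewer probes were well above background (51.0% and 52.4%), which limits folds of dim genes there.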

Other observations

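The values below were chosen after they were seen, and no explanation for them was tested. The 2 border-zone arrays M17 and M24 differed in red cell transcripts. The beta-globin Hbb-bs was at 4.69, -0.23 and 3.74 (normalized log2 signal) on M17, M24 and M25, against 5.04, 5.37 and 5.60 on C4, C5 and C6. Alas2, the erythroid enzyme of heme synthesis, was at 0.58, -4.35 and -0.45, and the alpha-globin Hba-a2 at -1.69, -5.81 and -2.67. Opposite to these, Fam111a was at -2.99, 2.15 and 1.27 and the lectin Reg3g at -3.57, -0.080 and -0.94. The chemokine Ccl20 was at 1.65, -1.49 and 0.78.

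Among genes with sham arrays within 2-fold that passed both pooled and with scan as a block, 599 rose and 634 fell. Beyond those already described, rises included Angptl4, an inhibitor of lipoprotein lipase (5.75 ± 0.44, 5.96 against C4), Mcemp1 (4.58 ± 0.17, 4.67 against C4), the ficolin Fcnb (4.29 ± 0.14, 4.11 against C4), the protease inhibitor Serpinb1a (4.25 ± 0.13, 4.11 against C4), the monocyte attractant Ccl2 (4.01 ± 0.20, 3.64 against C4) and the cholesterol hydroxylase Ch25h (3.88 ± 0.41, 4.19 against C4). Further falls were Mycn (-2.66 ± 0.28, -3.11 against C4), Smim5 (-2.64 ± 0.27, -2.64 against C4) and Calhm5 (-2.60 ± 0.17, -2.69 against C4). The limit to sham arrays within 2-fold itself keeps the standard errors of all these genes small, and the 2 fits share arrays.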
